A study of Bos indicus x Bos taurus and Bos indicus with 8 samples.

How the data were processed

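Gene expression was measured in blood mononuclear cells of crossbred and indigenous (Tharparkar) cattle, with or without exposure to Theileria annulata sporozoites for 2 h. Per the labels' protocols, each cell sample was divided and one part infected, total RNA was extracted, and 200 ng were labelled with Cy3 for a one-colour Agilent bovine (V2) 4x44K array. Groups and replicate numbers came from the sample labels, in which the second array of a group is marked as a replicate. Each of the 4 groups had 2 arrays, and this number limits the precision.

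The deposited scanner files hold intensity values of 1 array each. Per the file headers, spots were read with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 11.0.1. The processed signal is an intensity from which Feature Extraction had removed background, per the file headers; it was not scaled between arrays. The deposited files also give the median intensity of spot and local background and flags, among them whether a spot lay well above background, and 0 spots were saturated. The authors' table of the whole series holds log2 values per array. Set against the scanner files, each of its columns correlated with its own array at r = 0.9998 to 0.9999 over rows with 1 probe, and at most -0.05 with any other array of the breed. Its values are the processed signal relative to the array's 75th percentile, centred on the median of the 4 arrays of the breed and averaged over probes of a gene identifier. The breeds form separate blocks, so this table was used only within a breed. The medians of its columns were -0.12, 0.023, 0.0093 and 0.048 for indigenous control replicates 1 and 2 and infected replicates 1 and 2. They were 0.046, 0.019, -0.031 and -0.035 for the crossbred arrays in the same order. The words of its header do not state scale or centring, which were read from the values, and its direction is that of the scanner signal.

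Control spots and spots marked as outliers were left out, and spots of one probe were averaged on the log2 scale. Of 43653 distinct probes, 619 without a value on some array were dropped. The main setting was log2 of the processed signal minus each array's 75th percentile. Gene identifiers came from the probe names of the authors' table, which give one for 34852 probes and 17049 distinct identifiers. The probe with the highest mean over all 8 arrays stood for its gene identifier, and the 8801 probes without one were kept singly. Of the resulting 25680 features, the 16498 that were well above background on both arrays of at least 1 group were tested. None of the 27886 distinct sequence accessions and none of the gene identifiers matched the reference gene table used here (UOA_Brahman_1, 32783 genes). Gene symbols were therefore not used here, and the 28 gene lists fixed before the data were examined could not be applied.

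Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 arrays with 4 residual degrees of freedom, so that the groups share one estimate of the spread. The contrasts were infected minus control within each breed, the difference of these, and crossbred minus indigenous within control and within infected cells. An additive model of breed and infection gave the response common to both breeds, with 5 residual degrees of freedom. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over the 16498 features of 1 of the 6 comparisons. The rule for features to name, fixed before the data were examined, asked for gene symbols. Without them it was applied to probe identifiers and cut short to the 2 largest rises and 2 largest falls among called features with non-overlapping groups. Where a feature was not well above background on any array of a group, a fold is given as "at least". It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the feature's own signal and the lowest signal of any probe well above background.

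The steps were tested on simulated data, with the spread drawn from the fitted prior and 200 of the 16498 features changed by a known fold. Noise was independent between features and arrays, with no background floor, and all 200 changes had one size. The real arrays had deviations shared between groups, so these recovery rates and false calls need not hold for them. For infection in crossbred cells, 0 of 200 features changed 2-fold, 0 changed 4-fold and 177 changed 16-fold were recovered, with 8 false calls at 16-fold. In indigenous cells 172 of 200 changed 16-fold were recovered, and for the interaction 145. For the breeds, 169 in control cells and 182 in infected cells were recovered at 16-fold. For infection across both breeds, 147 of 200 changed 4-fold and 193 changed 16-fold were recovered.

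Arrays with the same replicate number deviated from their group means together: the correlation of these deviations over features was 0.472 between control and infected cells of crossbred cattle and 0.291 in indigenous cattle. It ranged from 0.234 to 0.423 between groups of different breeds. The labels' protocol says that each cell sample was divided between control and infection, so the replicate number was taken as a pairing within breed and run as a block. For infection across both breeds, this block was fitted with a separate infection effect per breed, and their average was tested. For the breed contrasts it entered as a correlation between arrays of one breed and replicate number, estimated at 0.340. The slide and scan, from the file headers, followed the breed and could not be run as a block. Slide positions followed condition and replicate. The spike-in spots lay near background, with at most 4.06% well above it on an array, and were not used for scaling.

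Alternatives fixed before the data were examined were quantile normalization, scaling to the median of probes detected on all arrays, no filter on dim probes, only probes detected on all 8 arrays, every probe tested alone, an intensity trend with robust spread, only the arrays compared, array quality weights, the replicate block, an unadjusted threshold with a 2-fold minimum, the authors' table, and leaving out each array. Background correction by normexp with an offset of 50 had been planned on mean signals. The files carry no such column, so it was run on median signals, a change made after seeing the data. A replicate block common to all groups and the removal of a smooth surface (loess over row and column, span 0.1) from each array were also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.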

Results

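Peripheral blood mononuclear cells, the lymphocytes and monocytes of blood, were taken from 2 kinds of cattle and exposed in culture for 2 h to sporozoites of Theileria annulata at 0.5 tick equivalents/ml. T. annulata is a tick-borne protozoan that enters bovine leukocytes and causes tropical theileriosis. The crossbred animals descended from Bos indicus and Bos taurus, and the indigenous animals were Tharparkar, a zebu breed. Control and infected cells of each kind were profiled on 2 one-colour arrays each, which gave 4 groups and 8 arrays. The series' design text calls the arrays of a group biological replicates and names no animal, so the p-values below measure the spread between these arrays. Between 54.3% and 68.2% of the distinct probes lay well above background on an array. The mean share was 66.3% ± 0.298 (SD, n = 2) in crossbred control cells and 65.8% ± 3.39 (SD, n = 2) in crossbred infected cells. It was 57.7% ± 3.21 (SD, n = 2) in indigenous control cells and 55.7% ± 2.03 (SD, n = 2) in indigenous infected cells. After a choice of 1 probe per gene identifier and a filter on dim probes, 16498 features were tested, 11733 of them with a gene identifier. The files pair probes with database sequences and numeric gene identifiers and not with gene names, so the features below carry the array's own probe and sequence identifiers.

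The first comparison asked which transcripts differed between infected and control cells of crossbred cattle. A_73_119222, a probe for the sequence NM_174690, rose from a mean signal of 9.68, not well above background on either array, to 28143 in infected cells. That rise was at least 1537-fold (adjusted p = 1.35e-05, limma). A_73_P245461, for NM_001079577, rose at least 942-fold (adjusted p = 0.000117), and the other probe of its gene identifier was higher by 7.06 on the log2 scale. A_73_101349, for Y18202, went the other way: its mean signal was 23414 in control cells and 6.19, not well above background, in infected cells, a fall of at least 1626-fold (adjusted p = 1.35e-05). Such a fall within 2 h would need a transcript half-life of at most 11.2 min, even with synthesis stopped at once. Whether both samples came from the same animals is taken up below. A_73_P052711, for ENSBTAT00000054377, fell at least 34.4-fold (adjusted p = 0.000117).

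In all, 88 features passed an adjusted p of 0.05 in crossbred cells, of which 38 rose and 50 fell. Their median fold was 6.46 with features that reached only a bound counted at it. In 39 of the 88, 19 of them higher in infected cells, the dimmer group was not well above background on either array. A second probe of the same gene identifier was available for 22 of the 88. It had the same sign in 21, against 65.7% of all genes with another probe, and in 16 of the 22 it changed at least 0.5 times as much in that direction. The 65.7% includes genes with small changes, and both probes were read on the same arrays. Here and below, such agreement bears on the measurement and not on its cause. At an unadjusted p under 0.05 there were 2241 features, where chance alone gives 825. Infected and control arrays also lay at different slide positions, so this excess need not come from infection. With the replicate number as a block within breed, 63 features were called, 33 higher and 30 lower, and only 44 of the 88 were among them. With a replicate block common to all groups, chosen after seeing the data, 247 were called, 126 of them higher, and all 88 were among them. In simulated arrays with independent noise, 88.5% of 200 features changed 16-fold were recovered for this comparison and 0% of those changed 4-fold. The smallest fitted fold among the 88 was 3.28, so the simulation sets no limit of detection for these arrays. The number called was 15 (8 higher) without crossbred control replicate 1, 36 (16 higher) without crossbred control replicate 2, 9 (6 higher) without crossbred infected replicate 1 and 16 (8 higher) without crossbred infected replicate 2, so the excess of falls did not hold in all of these.

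**Figure D1:**
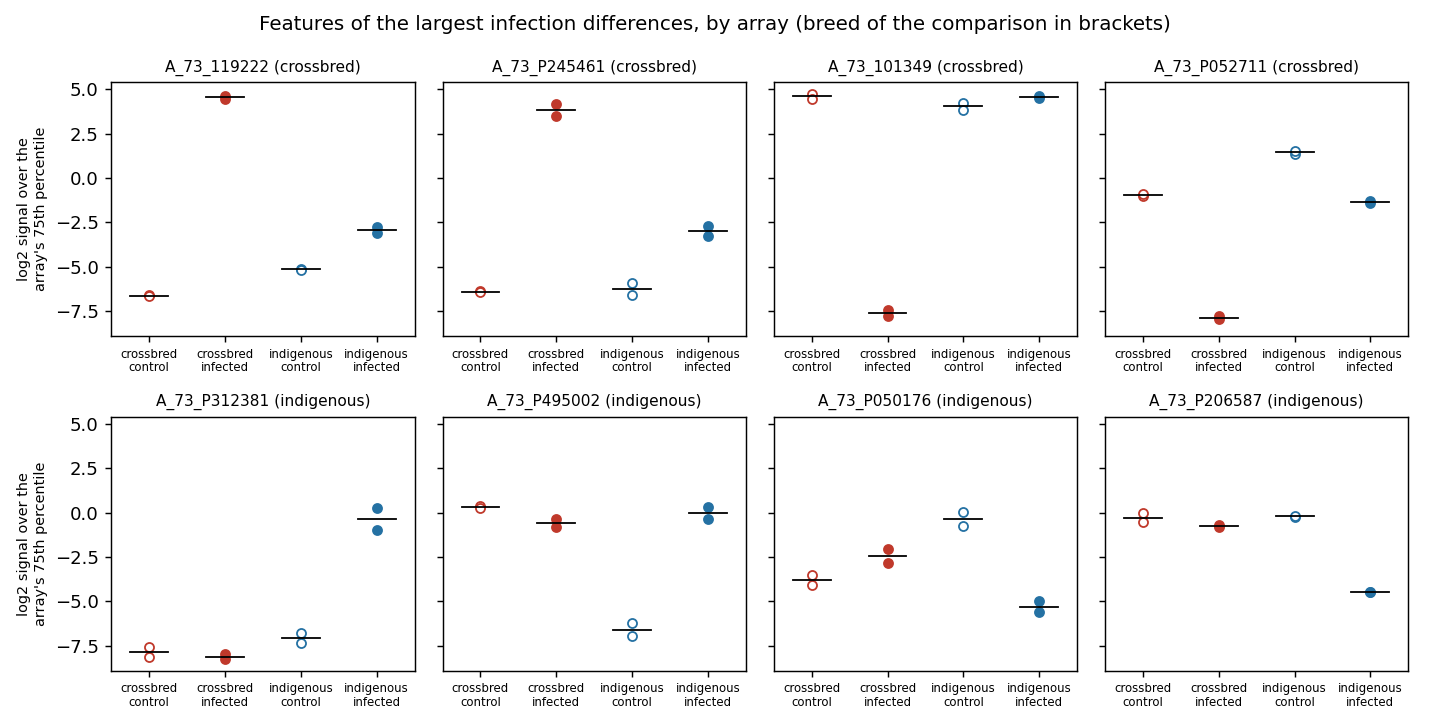
Each panel plots 1 feature, the vertical axis giving its log2 signal over the array's 75th percentile and the horizontal axis the 4 groups, with 1 point per array, open for control and filled for infected cells, and a bar at the mean of 2 arrays. The upper row holds the called features with the largest fitted rises and falls in crossbred cells and the lower row those in indigenous cells. Where a group lay at background, the fitted value is no bound and its rank is uncertain. A_73_101349 lay at a mean of -7.60 in crossbred infected cells and between 4.05 and 4.61 in the other 3 groups.

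The same comparison was made in indigenous cattle. A_73_P312381, for NM_001077829, rose at least 26.6-fold in infected indigenous cells (adjusted p = 0.00565), from a mean signal of 7.23, not well above background, to 589. A_73_P495002, a probe listed without a database sequence, rose at least 33.7-fold (adjusted p = 0.00565), from a mean signal of 9.96, not well above background, to 746. A_73_P050176, for NM_001078081, fell at least 24.2-fold (adjusted p = 0.0167). A_73_P206587, for XM_001250278, was well above background on all 4 arrays and fell 19.0-fold (adjusted p = 0.00565), from a mean signal of 834 to 34.3. A_73_P312381 and A_73_P050176 did not pass with normexp background correction, and A_73_P050176 and A_73_P206587 did not pass with the replicate block within breed. None of the 4 passed with only the arrays compared or without indigenous control replicate 2. A_73_P050176 and A_73_P206587 did not pass without indigenous infected replicate 2, nor A_73_P050176 without indigenous control replicate 1.

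Across all features, 64 passed an adjusted p of 0.05 in indigenous cells, of which 37 rose and 27 fell. Their median fold was 5.78 with bounded features at their bound. The dimmer group was not well above background on either array in 38 of the 64, and 5 of these reached a bound under 2-fold. A second probe was available for 17 and had the same sign in 14, against 61.1% of all genes with another probe; 9 of the 17 did so at an unadjusted p under 0.05 and 5 changed at least 0.5 times as much. There were 2338 features at an unadjusted p under 0.05. With the replicate number as a block within the breed, limma called 3 features, all higher in infected cells. With a replicate block common to all groups, chosen after seeing the data, it called 299, 152 of them higher, and all 64 were among them. The count thus depends on how the replicate number is treated. The number called was 15 without indigenous control replicate 1, 7 of them among the 64, and 3 without indigenous infected replicate 2. Without indigenous infected replicate 1 it was 51, but 15 were higher and 36 lower and only 18 were among the 64. Limma called 0 without indigenous control replicate 2, with 2089 features at an unadjusted p under 0.05.

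Whether the response differed between the breeds was tested with an interaction term. A_73_P114441, for ENSBTAT00000061050, rose by 6.57 on the log2 scale in crossbred cells and fell by 3.92 in indigenous cells, a difference of 10.50 ± 0.35 (SE, adjusted p = 0.000154, limma). With normexp background correction its interaction was 4.46 and did not pass (adjusted p = 0.105, limma, where its alternatives ranged from 0.000107 to 0.105). For A_73_119222 the rise in crossbred cells exceeded that in indigenous cells by 8.96 on the log2 scale (adjusted p = 0.000343). A_73_101349 had the opposite interaction of -12.73 (adjusted p = 0.000154): its signal was 15846 in indigenous control cells and 17726 in indigenous infected cells. For A_73_P495002 the interaction was -7.48 (adjusted p = 0.00724), with a rise in indigenous cells and a log2 difference of -0.90 in crossbred cells, and it did not pass without crossbred control replicate 1 or 2 or crossbred infected replicate 1. These log2 values are fitted ones, and where a group lay at background they are no bound.

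In total 59 features passed the interaction test, with a more positive response in crossbred cells for 31 and in indigenous cells for 28. Across the 16498 features, which are not independent replicates, the infection difference in crossbred cells correlated with that in indigenous cells at Pearson's r = 0.102 and Spearman's rho = 0.119. Pearson's r was -0.036 with normexp background correction, 0.036 with the surface removed and from 0.020 to 0.158 with 1 array left out, so its sign is not settled. No array was shared between these comparisons. Of the 88 features called in crossbred cells, 55 had the same sign in indigenous cells, and of the 64 called in indigenous cells, 29 had the same sign in crossbred cells, beside 54.1% of all features. With the replicate number as a block within breed, 14 features passed the interaction test, 8 of them with a more positive response in crossbred cells. With a replicate block common to all groups, chosen after seeing the data, 116 passed, and 58 of the 59 were among them. The count was 7 without crossbred control replicate 1, 5 without crossbred control replicate 2, 5 without crossbred infected replicate 1 and 7 without crossbred infected replicate 2. It was 23 without indigenous control replicate 1, 11 without indigenous control replicate 2, 25 without indigenous infected replicate 1 and 6 without indigenous infected replicate 2.

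**Figure D2:**
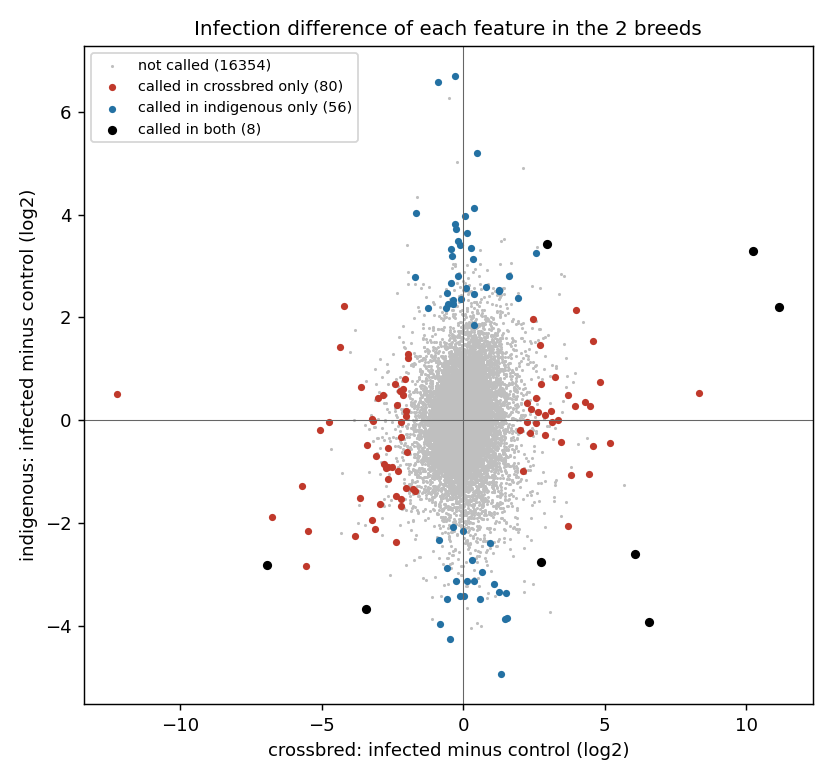
Each point is 1 of the 16498 features, with the infected minus control log2 difference in crossbred cells on the horizontal axis and in indigenous cells on the vertical axis, each a difference of means of 2 arrays; colours mark features called in crossbred cells only (80), in indigenous cells only (56) or in both (8). The called features lie mostly along one axis or the other, and Pearson's r over all features was 0.102.

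For infection, 8 features passed an adjusted p of 0.05 in both breeds. Of these 8, A_73_119222, A_73_P245461 and A_73_P046541 rose in both, against 0.0852 features that independent lists of these sizes give. A_73_P052711 and A_73_P102131 fell in both, against 0.0818 for such lists. A_73_P114441, A_73_P040092 and A_73_P482263 rose in crossbred and fell in indigenous cells, the last 2 named after their values were seen, against 0.174 in opposite directions for such lists. Both comparisons use one estimate of each feature's spread, so a feature with a small estimate tends to be called in both. The lists are not independent, and the excess over these values, also present in opposite directions, is no measure of a shared response. With the replicate number as a block within breed, 0 of the 8 were called in both breeds by limma: 6 were called in crossbred cells, and the adjusted p in indigenous cells ranged from 0.0513 to 0.0768. A replicate block common to all groups, chosen after seeing the data, kept the calls of all 88 and all 64 features. The 8 thus stayed called in both breeds under that block.

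The part of the response common to both breeds was estimated with an additive model of breed and infection on 4 infected and 4 control arrays. On both slides control arrays lay at positions 1 and 2 and infected arrays at positions 3 and 4. The model therefore cannot tell infection apart from slide position. A_73_P046541, for NM_001077926, rose 9.12-fold across both breeds (log2 difference 3.19 ± 0.22, SE, adjusted p = 0.0095), with 2.95 in crossbred and 3.43 in indigenous cells on the log2 scale. Its fold is a fitted one, since it was not well above background in indigenous control cells, and the other probe of its gene identifier had a log2 difference of 0.76 and did not pass. A_73_P035516, for NM_001100320, was well above background on all 8 arrays and rose 7.93-fold (adjusted p = 0.0325), although the other 2 probes of its gene identifier, with log2 differences of -0.11 and 2.09, did not pass. A_73_P204682, for DT826629, fell by 4.19 on the log2 scale (adjusted p = 0.035) and was not well above background in infected cells of either breed. A_73_P102131, for AJ512824, fell by 3.56 (adjusted p = 0.0126), with log2 differences of -3.44 in crossbred and -3.68 in indigenous cells, and was not well above background in indigenous infected cells. Neither A_73_P204682 nor A_73_P102131 passed with normexp background correction, A_73_P035516 and A_73_P204682 did not pass with no filter on dim probes, and A_73_P204682 did not pass with the surface removed.

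This model called 50 features, 20 higher and 30 lower in infected cells. A second probe was available for 16 of them and had the same sign in 15, against 59.5% of all genes with another probe; 13 of the 16 changed at least 0.5 times as much. There were 2279 features at an unadjusted p under 0.05. A split of the arrays by replicate number instead of infection, in the same model, called 42. The replicate block within breed was fitted with a separate infection effect per breed, and the average of the effects was tested. Its count is therefore not that of the additive model with a block added. It was 110, of which 59 rose and 51 fell, and 28 of the 50 were among them. Leaving out crossbred control replicate 1 left 2 features and leaving out crossbred control replicate 2 left 3. With any of the other 6 arrays left out (crossbred infected replicate 1 or 2, indigenous control replicate 1 or 2, indigenous infected replicate 1 or 2), limma called 0, with between 1927 and 2155 features at an unadjusted p under 0.05.

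The breeds were also compared within each condition. All 4 crossbred arrays lay on 1 slide and all 4 indigenous arrays on another, so breed and slide cannot be told apart in what follows. Among control cells, A_73_P495002 was at least 42.7-fold higher in crossbred cattle (adjusted p = 0.0018). A_73_P065141, for ENSBTAT00000020307, was higher in crossbred control cells by 6.89 on the log2 scale (adjusted p = 0.0184) and well above background on 1 of the 2 indigenous control arrays. A_73_113057, for NM_174176, was at least 79.4-fold lower in crossbred control cells (adjusted p = 0.0131), and both other probes of its gene identifier were lower, by -7.25 and -5.66 on the log2 scale, the second of which did not pass. A_73_114743, for NM_174437, was lower in crossbred control cells by a log2 difference of -7.66 (adjusted p = 0.00584) and well above background on 1 of the 2 crossbred control arrays. A_73_113057 did not pass with normexp background correction or without any 1 of the 4 control arrays. A_73_P065141 and A_73_114743 did not pass with only the arrays compared, nor A_73_P065141 without crossbred control replicate 1 or 2.

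Between breeds, 308 features differed in control cells, 171 higher and 137 lower in crossbred cattle, with a median fold of 4.50 with bounded features at their bound. In 144 of the 308 the dimmer group was not well above background on either array, and 33 of these reached a bound under 2-fold. The crossbred group was the brighter in 96 of the 144, on the slide where more probes lay above background. A second probe was available for 86 and had the same sign in 78, against 66.7% of all genes with another probe; 58 of the 86 changed at least 0.5 times as much. The count was 25 (7 higher) without crossbred control replicate 1, 32 (11 higher) without crossbred control replicate 2, 79 (43 higher) without indigenous control replicate 1 and 29 (14 higher) without indigenous control replicate 2. With only the arrays compared it was 24 (7 higher) and with no filter on dim probes 195 (88 higher), so the excess of higher features did not hold in most of these.

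Among infected cells, A_73_119222 was higher in crossbred cattle by 7.49 on the log2 scale (adjusted p = 0.000166), with mean signals of 28143 and 97.3. A_73_112168, for NM_001193190, was at least 48.4-fold higher (adjusted p = 0.000324) but did not pass with normexp background correction. A_73_101349 was at least 1570-fold lower in crossbred infected cells (adjusted p = 2.78e-05), and A_73_P312381 was at least 52.1-fold lower (adjusted p = 0.00181). In all 129 features differed, 82 higher and 47 lower in crossbred cattle, with a median fold of 5.55 with bounded features at their bound. The dimmer group was not well above background on either array in 64 of the 129. Of the 308 and 129 features called between breeds, 44 were called in both conditions. Of these, 18 were higher in crossbred cattle in both, 18 lower in both and 8 in opposite directions. Independent lists would give 0.850, 0.390 and 1.17. Both comparisons use one estimate of each feature's spread, so their lists are not independent. The excess, also present in opposite directions, is therefore no measure of a shared breed difference. The breed differences in control and in infected cells correlated across features at Pearson's r = 0.230 and Spearman's rho = 0.191. The count in infected cells was 37 (18 higher) without crossbred infected replicate 1, 31 (14 higher) without crossbred infected replicate 2, 73 (53 higher) without indigenous infected replicate 1 and 25 (15 higher) without indigenous infected replicate 2. With only the arrays compared it was 10 (4 higher).

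The features were further grouped by the kind of database sequence their probe was designed on, as curated RefSeq mRNA, predicted RefSeq RNA, Ensembl transcript, consensus sequence or other sequence. In none of the 6 comparisons did the share of called features in 1 of these 5 classes differ from that in the rest past an adjusted p of 0.05 (Fisher's exact test, two-sided, lowest Benjamini-Hochberg adjusted p = 0.273 over 30 tests). Of the 8499 features on curated RefSeq mRNAs, 34 were called for infection in crossbred cells, 17 in each direction, and 34 in indigenous cells, 24 of them higher and 10 lower.

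On both slides the control arrays occupied positions 1 and 2 and the infected arrays positions 3 and 4. The infected minus control difference varied smoothly over the array surface, with an SD of the smoothed map of 0.22 on the log2 scale on the crossbred slide and 0.29 on the indigenous slide. The map took 8.07% of the variance of the infection difference over 28221 probes in crossbred cells and 12.8% in indigenous cells. The maps of the 2 slides correlated at r = 0.679 over probes. With a smooth surface removed from each array, a choice made after seeing the data, the correlation of the infection response between the breeds was 0.036, and 105 features were called for infection in indigenous cells, 58 of them higher.

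**Figure D3:**
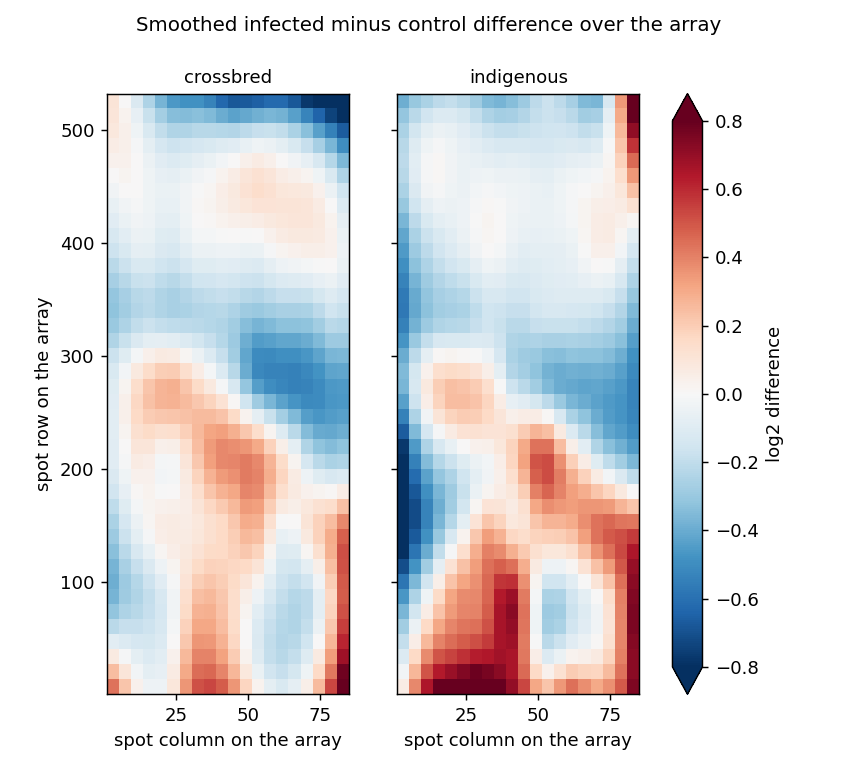
Each panel is 1 slide and breed, with spot column and spot row on the axes and colour giving the smoothed infected minus control log2 difference from 28221 probes, each a difference of means of 2 arrays. The maps ranged from -0.83 to 0.63 on the crossbred slide and from -0.97 to 0.99 on the indigenous slide at probe positions, and they correlated at r = 0.679; colours saturate at -0.8 and 0.8.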

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

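The test of whether switched features moved alike in both breeds, and the comparisons of array pairs, were set out before their values were seen but after single features of this kind had been noticed; the test on features switched in indigenous cells, the restriction to features able to fall, the shares of on-off features within a breed, the counts under other pairings of the arrays and the half-life were computed afterwards.

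A difference between the breeds in their response to infection flagged 59 features, among them A_73_P114441 with an interaction of 10.50, A_73_119222 with 8.96, A_73_101349 with -12.73 and A_73_P495002 with -7.48 on the log2 scale. With normexp background correction the interaction of A_73_P114441 was 4.46 and did not pass. All 4 were well above background on both arrays of at least 1 group and not on either array of another. Such switches were counted over all features, as both arrays of one group well above background, neither array of the other, and every array at least 3 on the log2 scale apart. Between control and infected cells, 27 features switched in crossbred cattle, 15 of them on in infected cells, and 19 in indigenous cattle, 11 of them on in infected cells. Between groups of different breeds the count was from 36 to 45.

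Chance scatter of dim probes is left open, because the filter bears on each comparison made of it. Pairs of arrays of one group differed by on-off features 40.6% as often as pairs of different groups, most of them pairs of different breeds. That share is under the 50% set beforehand for scatter. Within a breed the share was 36.0% of control-infected pairs in crossbred cattle but 56.9% in indigenous cattle. The latter is above 50%, although the bound was not set for shares within a breed. Features were kept only if well above background on both arrays of at least 1 group. A feature that parted the 2 arrays of a group stayed only if another group passed. This lowers these shares, so a low share cannot argue against scatter. Switched features need both replicates alike. Pairing the arrays of a breed by replicate number instead gave 3 switched features in crossbred and 2 in indigenous cattle, while the crossed pairing gave 0 in each. A feature switched under these pairings passed the filter only through a group of the other breed, so the low counts cannot decide either. A response common to both breeds stays open. Only 1 feature switched in both breeds. Of the 27 features switched in crossbred cells, 8 moved at least 2-fold the same way in indigenous cells, 29.6%, with an exact 95% interval from 13.8% to 50.2%, and 6 moved the opposite way. Of the 19 switched in indigenous cells, 4 moved the same way in crossbred cells, 21.1%, with an interval from 6.05% to 45.6%, and 4 the opposite way. That second interval lies below 50%, the bound set for the first. Of all features tested, 16.4% in indigenous and 14.1% in crossbred cells differed at least 2-fold between infected and control cells, in either direction. The bound does not allow for these shares, so lying below it does not decide against a common response. Such a response also stays open because a fall cannot be seen in a feature not well above background on both control arrays of the other breed. Without such falls the shares were 8 of 21 (18.1% to 61.6%) and 4 of 16 (7.27% to 52.4%). Another candidate explanation, against the labels' protocol, in which each cell sample was divided between control and infection, is that control and infected cells of a breed did not come from the same animals. Control and infected arrays of one breed differed in 79.3% as many on-off features as arrays of different breeds (means 125 and 158), as that would give. Arrays of one group still differed in 37.8% as many, a share that the filter lowers. A response particular to each breed would give the same, so these cannot be told apart. For A_73_101349 a fall of at least 1626-fold within 2 h would need a transcript half-life of at most 11.2 min even if its synthesis had stopped at once.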

How the results depend on the processing

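Counts are given in the order infection in crossbred cells (88 features), infection in indigenous cells (64), interaction (59), breed in control cells (308), breed in infected cells (129) and infection across both breeds (50); normexp on median signals, the common block and the surface removal were chosen after seeing the data. Quantile normalization, median scaling and array quality weights kept each of the 6 counts within 1.5 times. With 2 arrays per group most other choices did not, and the cause was not tested unless the setting's construction gives it. The array weights were equal within each group, from 0.981 to 1.012, so they could not weigh down a single array. Median scaling shifted the infection differences by only 0.013 in crossbred and 0.025 in indigenous cells on the log2 scale. These 2 settings lie close to the main one and are weak checks. Normexp gave 30, 13, 12, 54 and 41 in the first 5 comparisons. No filter on dim probes, with more features tested, gave 41, 23, 21 and 195 in the first 4 and 2 across both breeds. Only probes above background on all arrays, which removes features that go to background, gave 4, 8, 10, 74 and 32 in the first 5. Every probe tested alone gave 135 and 126 for infection in each breed and 87 across both. The intensity trend with robust spread gave 35 for the interaction and 205 for control cells. With only the 4 arrays compared, and so fewer degrees of freedom, the counts were 19 for infection in crossbred cells, 24 for breed in control and 10 in infected cells, and limma called 0 for infection in indigenous cells, with 2031 at an unadjusted p under 0.05. In the authors' table limma called 18 features for infection in crossbred cells and 0 in indigenous cells, with 2060 at an unadjusted p under 0.05 in the latter. An unadjusted p under 0.05 with at least 2-fold gave 1494, 1677, 1776, 2150, 1485 and 945.

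With the replicate block within breed the counts were 3 for infection in indigenous cells, 14 for the interaction and 110 across both breeds. No other count moved by over 1.5 times, although for infection in crossbred cells it called 63, only 44 of them among the 88. Across both breeds this setting tested the average of a separate effect per breed, and for the breed comparisons the block entered as a correlation. The replicate block common to all groups gave 247, 299, 116, 908, 238 and 98. With the smooth surface removed, infection in indigenous cells had 105, and together with the common replicate block the counts were 429, 429, 230, 1351, 426 and 112. Leaving out 1 array, with the lone array of a group assumed to vary like the other groups, gave 9 to 36, 0 to 51, 5 to 25, 25 to 79, 25 to 73 and 0 to 3. The correlation of the infection response between breeds, 0.102, was 0.036 with the surface removed and -0.036 with normexp, and 0.020 to 0.158 with 1 array left out. Of 416 values of the 24 named results under other settings or probes, 350 kept direction and call, 65 kept direction only, 43 of them with 1 array left out, and 1 changed sign: another probe of the gene identifier of A_73_P035516, at -0.11. The slide as a block could not be fitted, since each slide held 1 breed, and the gene lists could not be run without symbols. Signal over background limits the folds: of the features called for breed in control cells, 144 reached only a bound.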

Other observations

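The tests of a shared animal, of the array surface and of a shared day in the second paragraph were chosen after the correlations had been seen, and the restriction to balanced splits in the last paragraph after the counts had been seen; the others were set out beforehand.

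The differences between replicate numbers 1 and 2 were partly alike in all 4 groups. The correlation of these deviations averaged 0.360 over the 6 pairs of groups. Their covariance, averaged over these pairs, was about 35.9% of their mean variance within a group. Cells of one animal split between cultures are argued against as the whole cause, since the 4 pairs of groups of different breeds, which share no animal, averaged 0.349 (bootstrap 95% interval over features 0.332 to 0.366). A smooth trend over the array surface is argued against too, with a mean of 0.411 once it was removed, as is a bias that depends on signal, with 0.358 once a trend on mean signal was removed. A shared day of culture, labelling or hybridization for each replicate number may be the source, as may slide position. On both slides replicate 1 lay at positions 1 and 3 and replicate 2 at positions 2 and 4. These cannot be told apart from each other or from other sources. The labels and headers give no batch that follows the replicate number, and both of the 2 slides hold both replicate numbers. With the replicate number as a block common to all groups, the counts were 247 for infection in crossbred and 299 in indigenous cells.

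The smoothed map of the infection difference was alike on the slides of both breeds. If spot position set it, probes of one gene printed at different places should follow the map made from other genes, and if genes with like responses lay near each other they should not. Among 18476 probes of 6822 gene identifiers, the slope of a probe's infection difference, less its gene's mean, on that map was 1.06 (bootstrap 95% interval 1.031 to 1.099). That argues against a grouping of genes and is consistent with an effect of spot position, in slides where infected cells always lay at positions 3 and 4. The signal of the bright corner spots, control spots of the array design, fell in the same order on both slides, from log2 values of 4.05 and 3.84 over the 75th percentile in crossbred control to 2.84 and 1.75 in crossbred infected arrays, and from 3.25 and 3.17 to 2.71 and 1.37 in indigenous ones. Part of the correlation of 0.102 between the breeds' responses may therefore come from position, since it was 0.036 with the surface removed.

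The 50 features called for infection across both breeds were set against other splits of the 8 arrays into 4 and 4, in the same model with breed. Of the 34 splits that could be fitted, 1 gave as many, the real one, a share of 2.94%, under the 5% set beforehand. But 16 of the 34 put 3 arrays of a breed on one side and are not like the design. Of the 18 with 2 arrays of each breed on each side, again only the real one gave as many, and 18 splits are too few for a share under 0.05, as are the 8 that part every replicate pair. The highest other count was 42, from the split by replicate number, and all remaining splits gave 0; among the 8 that part every replicate pair the highest other count was 0. The real split is also the split by slide position.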
